A study of Mus musculus with 12 samples.

How the data were processed

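RNA was measured by high-throughput sequencing of spleens from 8-week-old ICR mice, in 12 libraries that form 4 groups of 3: control, busulfan, L.J. at 10 mg/kg, and busulfan with L.J. at 10 mg/kg. Per the labels' protocols, the spleens were frozen in liquid nitrogen, RNA was extracted with Trizol and a kit, and libraries were built from total RNA by standard Illumina methods. The deposited file is 1 table of 21004 genes with an NCBI Gene number, a symbol and 1 FPKM value per library (fragments scaled by transcript length and by the mapped fragments of the library), rounded to 2 decimals, per the file headers. The submitters' processing notes name Bowtie 0.12.2 and the mouse genome build mm10, without saying what each was used for. The counting tool, the gene annotation, the handling of strand and any filter on genes are not given in the sources used here. FPKM divides each gene by its length and by the total of its library, so a few very abundant transcripts in 1 library lower the values of all its other genes.

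Each column was matched to its sample by name, and no column was left unmatched. Groups and replicate numbers were taken from the labels. For 26 genes a spreadsheet had turned the symbol into a date, and these symbols were restored through the gene number, since 99.2% of the gene numbers were found in the RefSeq gene table. Coordinates of named genes are from the same RefSeq gene table, on the assembly of mm10, counted from 1. Reads shared between near-identical genes cannot be traced in FPKM values, so members of the Stfa, Mup, Klra, Amy2, Ear, beta-globin and ribosomal protein families, and genes with an overlapping partner on the other strand, carry that uncertainty.

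The sequencing depth is unknown. The deposited FPKM values of 164 sparse genes were searched for steps of whole fragments from 20 starting points. Between 50.9% and 67.9% of the values came out whole within 0.1, and the relative depth of 1 library varied up to 1.77-fold between starting points, so no read numbers were recovered and no count test was run. The deposited FPKM values sum to between 511876 and 580364 per library, and between 12249 and 13129 genes reach 1 FPKM. Among 6922 genes with a mean of at least 10 FPKM, 31 are listed at 0 in at least 1 library, most of them pancreatic or neutrophil genes.

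The analysis used log2(FPKM + 1), so that differences of weakly expressed genes are understated. Genes with a mean of at least 1 FPKM in at least 1 group were kept, which left 13138. A model with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (limma-trend with robust empirical Bayes), and 5 contrasts were tested with Benjamini-Hochberg adjustment at a threshold of 0.05. The 4 groups share 1 estimate of the spread. Gene lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over the lists of a contrast. Of 44 lists of cell types, neighbouring tissues and pathways, 41 had at least 5 tested genes. A list score is the mean log2(FPKM + 1) of its genes in 1 library. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

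Design, lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule names, per contrast, up to 8 genes with the highest and up to 8 with the lowest log2 difference among called genes whose groups do not overlap, 3 members with the smallest p of up to 8 lists past the threshold, the 10 genes with the smallest p where fewer than 10 were called, and 9 fixed markers, leaving predicted genes and receptor segments out of its first part. Not every gene that the rule picks is named. Other genes are named as chosen after their values were seen. A further 4 lists (islet, kidney tubule, spermatid, and fatty acid oxidation with PPAR targets) were written after a first look at the data.

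The scripts were tested on simulated data for the contrast of L.J. in busulfan-treated mice, with 200 of 13138 genes changed. A log2 change of 0.5 was called in 38% of the genes that carried it, 1 in 80%, 2 in 94% and 3 in 98%, all with the right sign, beside 10 unchanged genes called. The simulated noise was independent between genes, with 1 SD per gene in all groups, and changed genes were drawn above a mean of 5 FPKM. Real genes are correlated and the busulfan libraries spread most, so these shares may not hold for the real contrast. Correlations of log2(FPKM + 1) ranged from 0.915 to 0.986 for the 12 pairs of libraries within groups and from 0.873 to 0.985 for the 54 pairs across groups, so no pair held identical values. Alternatives were quantile normalization, median of ratios scaling, library weights, no robust option, no filter, a mean of at least 5 FPKM, pseudocounts of 0.1 and 5, only the groups compared, each library left out, the replicate number as a block, and an absolute log2 difference of at least 1. Added after seeing the data were the acinar score as a covariate and a fit without busulfan libraries 1 and 2 and L.J. library 3, whose acinar score is above 5.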

Results

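Spleen RNA was compared between control mice, mice given busulfan, mice given L.J. at 10 mg/kg and mice given both, with 3 libraries per group. Busulfan is an alkylating agent that damages dividing cells and is used to empty the bone marrow before a transplant. The labels do not spell out L.J., and give neither the busulfan dose nor the time between treatment and collection. The description of the series also speaks of effects of FMT, an abbreviation that it does not spell out and that no sample label gives, so whether FMT was part of any treatment is unknown, and groups are taken as labelled. The series title frames the question as whether L.J. counters the harm that busulfan does to the spleen. Values are FPKM without read numbers, so the depth behind each value is unknown. No label states that the libraries of a group came from separate mice, and p-values therefore measure the spread between these libraries. Hbb-bs and Hbb-bt made up 31.6%, 0.41% and 51.1% of adult beta globin FPKM in busulfan libraries 1 to 3. With both agents they made up 48.8%, 0.85% and 38.8%, and in controls 0.18%, 46.9% and 19.0%. Such values argue against repeats of the same RNA sample in those groups. With L.J. alone the shares were 49.2%, 47.2% and 50.3%, which do not tell the libraries apart. Their pancreatic acinar scores of 3.41, 1.42 and 5.64 argue against repeats of the same RNA sample. Parts of the same spleen could still differ in this way, so the spread there may not be that between mice. Ddx3y, a gene of the Y chromosome, was above 1 FPKM in all 12 libraries.

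Transcripts of organs other than the spleen differed widely between the libraries. Amy2a5, a pancreatic amylase, stood at 19030 FPKM in busulfan library 1, 1484 in busulfan 2 and 55.8 in busulfan 3. It was at 167, 19.2 and 1177 FPKM in L.J. libraries 1 to 3, at 32.2 in library 3 of busulfan with L.J., and below 1 in the other 2 libraries of that group and in all 3 controls. Acinar genes made up 11.1% of the FPKM sum in busulfan 1, 1.02% in busulfan 2 and 1.29% in L.J. 3. Liver genes were higher in the controls, where the hepatocyte score was 2.28 ± 0.65 (SD, n = 3), against 1.11 ± 0.13 with busulfan, 1.39 ± 0.06 with L.J. and 1.17 ± 0.09 with both. The first principal component, with 42.9% of the variance, placed busulfan 1 at -71 and busulfan 2 at -30.5, and the other 10 libraries between -16.2 and 24.7.

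**Figure D1:**
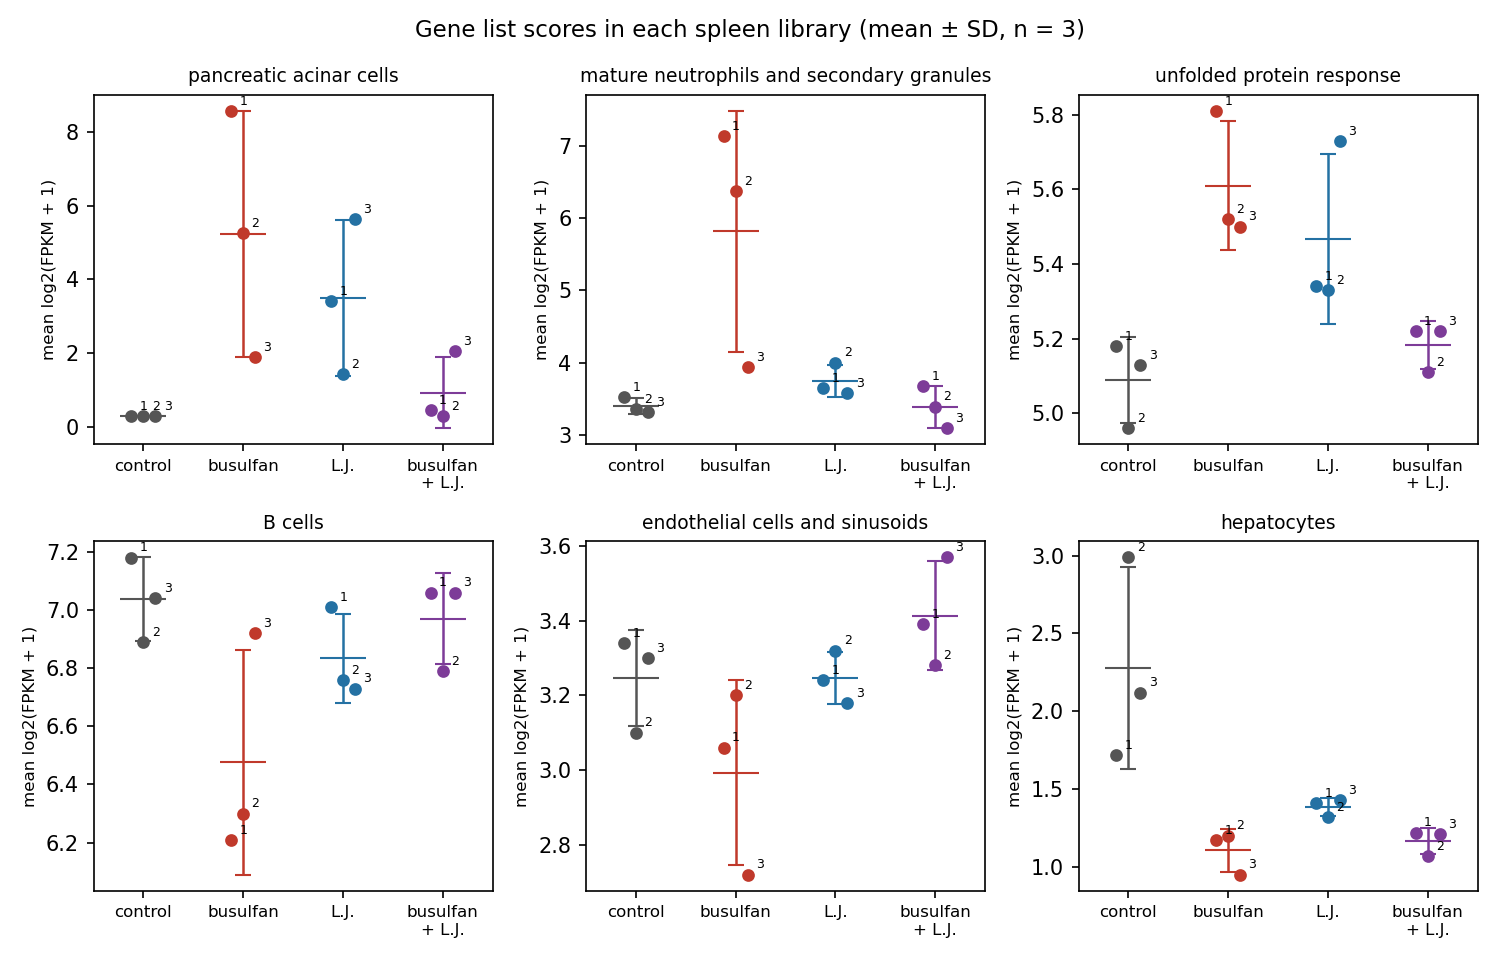
Mean log2(FPKM + 1) of 6 gene lists in each of the 12 spleen libraries, with points numbered by replicate and bars giving the group mean ± SD (n = 3). Busulfan libraries 1 and 2 stand at 8.56 and 5.25 for acinar genes and 7.13 and 6.37 for neutrophil genes, while busulfan 3 is at 1.89 and 3.94.

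Busulfan against control asks what busulfan alone did to spleen transcripts. Slpi, an inhibitor of neutrophil serine proteases (gene 20568, chromosome 2, 164354070 to 164356507), rose from 49.7 ± 9.6 to 667 ± 436 FPKM (SD, n = 3), a log2 difference of 3.49 (SE 0.42, limma adjusted p = 0.0248). Prg2, the eosinophil major basic protein (gene 19074, chromosome 2, 84980461 to 84983632), rose from 3.49 ± 1.31 to 36.8 ± 18.7 FPKM, a log2 difference of 2.99 (SE 0.38, limma adjusted p = 0.0285). Slc34a1, a phosphate transporter of the kidney tubule (gene 20505, chromosome 13, 55399622 to 55414695), fell from 3.09 ± 1.14 to 0.45 ± 0.03 FPKM, a log2 difference of -1.47 (SE 0.19, limma adjusted p = 0.0309). These 3 were among the 4 genes called, 2 higher and 2 lower, of 13138 tested, of which 1602 had an unadjusted p below the threshold. Next in p came Gucy1a1, a subunit of the nitric oxide receptor (-0.70), Keg1 and Kap, both genes of the kidney (-1.13 and -2.42), Edaradd, an adaptor of ectodysplasin signalling (-0.78), and LOC105247075, a gene without a settled name (1.77), each with a limma adjusted p of 0.052.

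Granulocyte transcripts stood far higher in busulfan libraries 1 and 2 and little higher in busulfan 3. S100a8, an abundant neutrophil protein, was at 7700, 2424 and 237 FPKM in the 3 busulfan libraries and at 123 ± 45.5 FPKM in the controls (limma adjusted p = 0.238). Of 29 tested genes of mature neutrophils, 27 were higher, with a median log2 difference of 2.37, and of 15 genes of granulocyte precursors all 15 were, with a median of 2.54. Mpo, the myeloperoxidase of primary granules, differed by 3.61 (SE 1.02, limma adjusted p = 0.253), Elane, neutrophil elastase, by 3.65 (adjusted p = 0.244) and Stfa2, a stefin, by 6.02 (adjusted p = 0.124). None of the genes of either list passed over all genes tested, and 24 of the neutrophil and 13 of the precursor genes did when adjusted over the list alone. Both lists were past the threshold of camera with the preset correlation, and had an adjusted p = 0.262 with an estimated correlation. The 2 libraries with the highest values also had the 2 highest acinar scores of the group.

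The lists of the unfolded protein response and of plasma cells passed camera with the preset correlation. Both had an adjusted p = 0.262 with an estimated correlation, and neither passed fry (adjusted p = 0.0512 and 0.0824). In the former 28 of 29 genes were higher, with a median of 0.48, and 17 passed when adjusted over the list alone, none over all genes. Manf, a factor secreted upon stress of the endoplasmic reticulum, was at 110 ± 14.8 against 64.7 ± 5.03 FPKM (limma adjusted p = 0.115), Creld2, another such gene, at 79.8 ± 10.6 against 31.95 ± 4.8 (adjusted p = 0.124) and Derl3, a component of the degradation machinery of that compartment, at 36.5 ± 9.43 against 11.02 ± 3.48 (adjusted p = 0.135). Of 13 plasma cell genes 12 were higher, with a median of 0.87, and 8 passed adjusted over the list alone. For that list 25 symbols were written, among them immunoglobulin constant genes and synonyms, and 13 genes were found. Creld2 belongs to both lists, so they are not independent of each other. Xbp1, the transcription factor of secretory cells, differed by 1.29 (limma adjusted p = 0.167). Pancreatic acinar genes, which are also those of a secretory cell, had a median difference of 5.69 in the same comparison, with all 36 higher and 31 past the threshold when adjusted over the list alone (adjusted p = 0.262 with an estimated correlation).

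B cell genes were lower with busulfan in all 29 tested members, with a median of -0.59, and 17 passed adjusted over the list alone and none over all genes. Blk, a B cell kinase, differed by -0.87 (limma adjusted p = 0.153) and Cr2, a complement receptor, by -0.80 (adjusted p = 0.211). The B cell list had an adjusted p = 0.262 with an estimated correlation, and its scores of 6.21 and 6.30 in busulfan libraries 1 and 2 were below the 6.92 of busulfan 3. All 19 hepatocyte genes were lower, with a median of -1.28, and 16 passed adjusted over the list alone (adjusted p = 0.262 with an estimated correlation). Alb, serum albumin, was at 1.69 ± 0.67 against 18.7 ± 13.9 FPKM (limma adjusted p = 0.057). Genes of oxidative phosphorylation were higher in 48 of 51 members, with a median of 0.21 (adjusted p = 0.367 with an estimated correlation), none of which passed even when adjusted over the list alone. That median was -0.049 with the acinar covariate and -0.004 without the 3 high acinar libraries. Cdkn1a, the cell cycle inhibitor induced by p53, stood at 22.2 ± 2.04 against 15.02 ± 2.66 FPKM (limma adjusted p = 0.259), and the list of p53 target genes did not pass camera, with a median of 0.08 and an adjusted p = 0.107. The proliferation marker Mki67, the T cell gene Cd3e, the red pulp macrophage factor Spic and the collagen gene Col1a1 differed by -0.15, -0.14, -0.01 and -0.35, and the erythroid haem enzyme Alas2 by -0.32, with limma adjusted p between 0.638 and 0.985. Mitosis genes were higher in 42 of 46 members (median 0.22) and DNA replication genes in 35 of 42 (median 0.10). Erythroid genes were lower in 35 of 38 (median -0.50, and 0.26 with the acinar covariate). These lists passed camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.506, 0.704 and 0.636). None of their genes passed over all genes.

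In all, 25 of 41 lists passed camera with the preset correlation, 15 higher and 10 lower, none passed with an estimated correlation and none passed fry (smallest adjusted p = 0.0512). The gene count was 829 without busulfan 3, 12 without control 1, 0 without control 2, 2 without control 3, 107 with library weights, 24 without the filter, 2 with a mean of at least 5 FPKM, 1 with a pseudocount of 0.1, 0 with only the groups compared, 0 with the acinar score as a covariate and 1 without the 3 libraries of high acinar score.

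L.J. in busulfan-treated mice, the comparison closest to the question of the series, gave the most called genes in the fit reported here. It did not with only the groups compared or the acinar covariate, which both gave 0. Nor did it without the 3 libraries of high acinar score, a fit that leaves 1 busulfan library. Without the filter it gave 18, against 24 with busulfan, 23 with L.J. alone and 30 for mice given both against control. Without library 1 or 2 of busulfan with L.J. it gave 2 each, against 3 and 4 for mice given both against control. Among 218 genes, 142 were higher and 76 lower in mice given both than in mice given busulfan alone. Angptl4, a secreted inhibitor of lipoprotein lipase and a target of PPAR receptors (gene 57875, chromosome 17, 33774900 to 33781575), rose from 2.78 ± 0.44 to 9.88 ± 0.46 FPKM (SD, n = 3), a log2 difference of 1.53 (SE 0.13, limma adjusted p = 0.00135). Cpt1a, which admits long-chain fatty acids to the mitochondrion (gene 12894, chromosome 19, 3322326 to 3385735), rose from 13.3 ± 1.25 to 29.2 ± 2.21 FPKM, a difference of 1.08 (SE 0.10, limma adjusted p = 0.00192). Cpt1a was chosen for this comparison after its value was seen. All 3 libraries with both agents lay above all 3 with busulfan alone for both genes. The naming rule requires this of Angptl4, and Cpt1a was chosen with its values seen, so the separation adds no support.

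**Figure D2:**
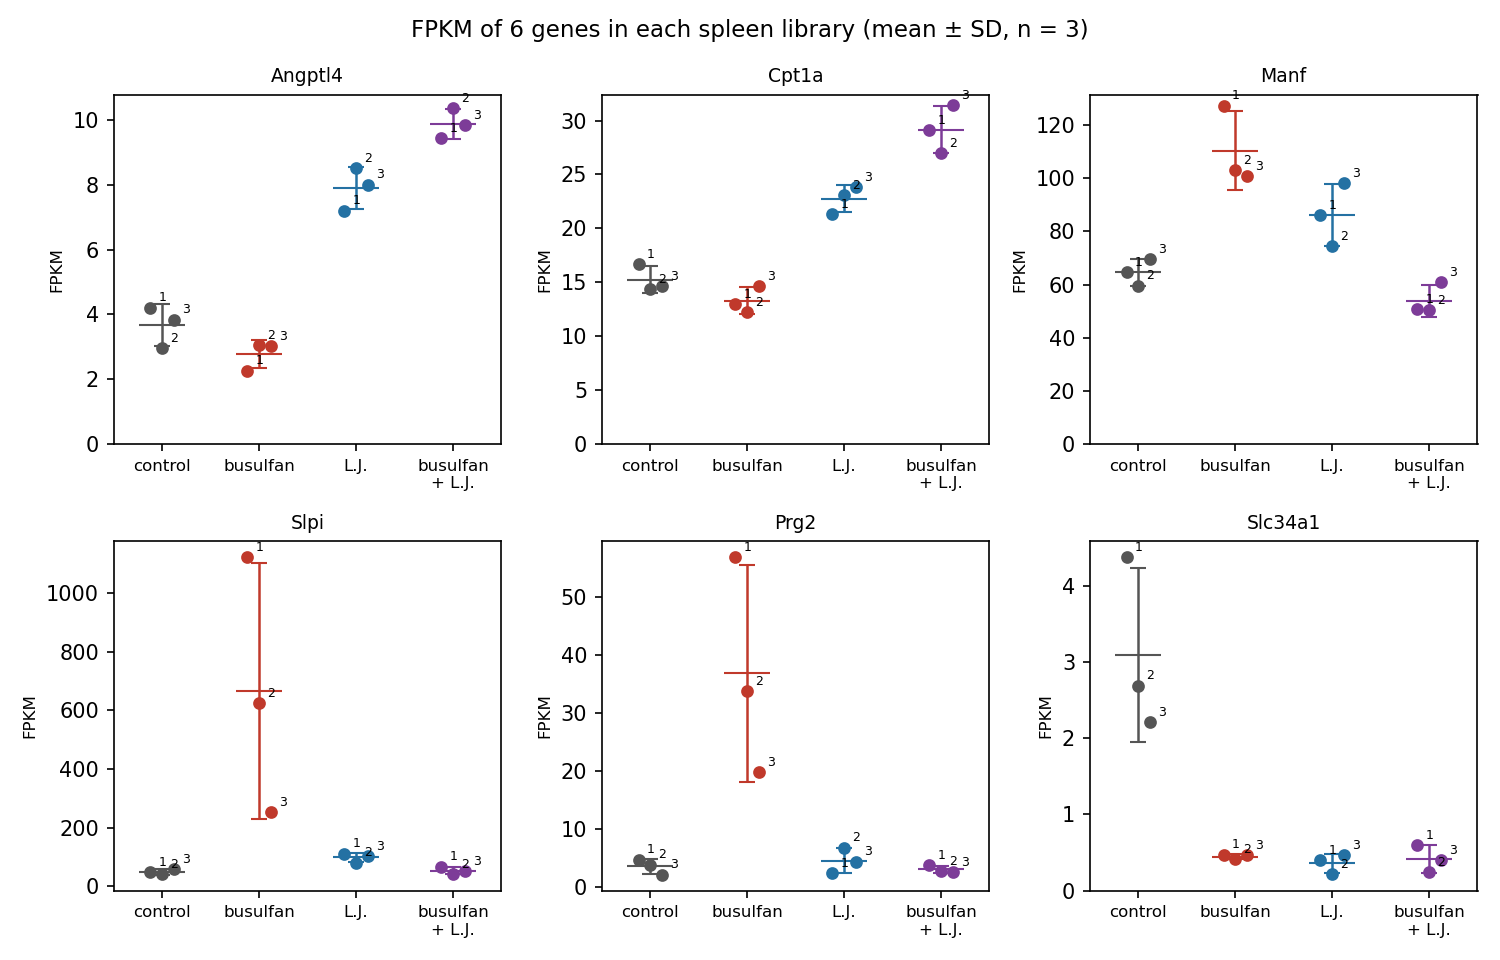
FPKM of Angptl4, Cpt1a, Manf, Slpi, Prg2 and Slc34a1 in each of the 12 spleen libraries, with points numbered by replicate and bars giving the group mean ± SD (n = 3). Angptl4 is between 7.2 and 10.4 FPKM in the 6 libraries with L.J. and between 2.27 and 4.21 in the 6 without it.

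A few vascular and stromal genes rose in this comparison, while most members of their lists did not pass. Of 28 tested genes of endothelial cells and sinusoids, 24 were higher, with a median of 0.43, and 5 rose over all genes (11 adjusted over the list alone). These were Stab2, a scavenger receptor of sinusoidal lining (0.99, limma adjusted p = 0.0197), Tek, the angiopoietin receptor (0.94, adjusted p = 0.0372), Stab1 (0.86, adjusted p = 0.0377) and, chosen after their values were seen, Kdr (0.76) and Mmrn2 (0.58). Stab2 went from 9.14 ± 1.91 to 19.0 ± 1.96 FPKM, Tek from 2.22 ± 0.73 to 5.05 ± 0.18, and the controls were at 13.1 ± 0.98 and 3.42 ± 0.31. The list had an adjusted p = 0.521 with an estimated correlation. Of 35 stromal genes 28 were higher, with a median of 0.26 (adjusted p = 0.737 with an estimated correlation), and 4 rose, among them the collagen genes Col3a1 (1.00) and Col1a2 (0.64), again chosen after their values were seen. Igfbp7, a protein of vascular matrix, rose from 242 ± 17.2 to 512 ± 38 FPKM (1.08, limma adjusted p = 0.0152).

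Lymphocyte lists went both ways with both agents. T cell genes were lower in 21 of 32 members (median -0.07) and germinal centre B cell genes in 9 of 12 (median -0.28), and neither of these 2 lists passed camera. In the B cell list 27 of 29 genes were higher, with a median of 0.53. Cd79b, a chain of the B cell receptor (1.03, limma adjusted p = 0.0441), and Fcrla (1.06, adjusted p = 0.0377) rose over all genes, and 15 passed adjusted over the list alone (adjusted p = 0.637 with an estimated correlation). The B cell scores of 6.21 and 6.30 in busulfan 1 and 2, which had the highest acinar and neutrophil scores of these 6 libraries, were below the 6.79 to 7.06 with both agents, and the 6.92 of busulfan 3 was within that range. Genes of cytotoxic lymphocytes and natural killer cells were higher in 25 of 28 members, with a median of 0.74, and 12 passed adjusted over the list alone (adjusted p = 0.521 with an estimated correlation). Their score was 2.09 in both busulfan 1 and 2 and 2.66 in busulfan 3, against 2.83 to 2.97 with both agents. Of these genes, Klrb1c, the natural killer receptor NK1.1, rose over all genes from 0.92 ± 0.56 to 3.05 ± 0.82 FPKM (1.10, limma adjusted p = 0.0409). Samd3, Cbr2, Ltc4s, Sema3d and Unc5cl, which belong to no list, rose by between 1.13 and 1.57.

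Granulocyte lists were lower in this comparison, with few members past the threshold. In the neutrophil list 27 of 29 genes were lower, with a median of -2.39, and 4 fell over all genes (24 adjusted over the list alone). These were Stfa2 (-5.92), BC100530 (-6.21), Pglyrp1, a bactericidal granule protein (-3.10), and Cxcr2, the receptor that draws neutrophils to chemokines (-1.03), with limma adjusted p between 0.0377 and 0.0484. The list had an adjusted p = 0.521 with an estimated correlation. Prg2 (-3.14, limma adjusted p = 0.0135), Epx, eosinophil peroxidase (-1.93, adjusted p = 0.0377), and Ear6, an eosinophil ribonuclease (-1.82, adjusted p = 0.0193), fell, as did Slpi (-3.38, adjusted p = 0.0135), Ckap4, a membrane protein of the endoplasmic reticulum (-1.92, adjusted p = 0.0395), and Gca, the calcium-binding grancalcin of neutrophils (-1.90, adjusted p = 0.0484). Prg2 and Epx belong to the list of mast cells and basophils, which also holds eosinophil genes. Of its 14 genes 12 were lower, with a median of -0.55, and Prg2 and Epx fell and Cma1, a mast cell chymase chosen after its value was seen, rose over all genes (3 lower and 1 higher adjusted over the list alone, adjusted p = 0.521 with an estimated correlation). The median was 0.074 without the 3 high acinar libraries. All 15 granulocyte precursor genes were lower, with a median of -2.62, none over all genes and 12 when adjusted over the list alone (adjusted p = 0.521 with an estimated correlation). S100a8 differed by -3.26 and Mpo by -3.27 (limma adjusted p = 0.111 and 0.108). All 36 acinar genes were lower, with a median of -4.93, none over all genes and 27 when adjusted over the list alone (adjusted p = 0.521 with an estimated correlation), so acinar and granulocyte transcripts differed in the same direction.

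The unfolded protein response list was lower as well, with most members not past the threshold. In it 26 of 29 genes were lower, with a median of -0.40, and 3 fell over all genes (15 lower and 1 higher adjusted over the list alone). They were Manf, from 110 ± 14.8 to 53.98 ± 5.98 FPKM (-1.02, limma adjusted p = 0.0164), Calr, the chaperone calreticulin (-0.66, adjusted p = 0.0396), and Creld2 (-1.15, adjusted p = 0.0484). The list had an adjusted p = 0.521 with an estimated correlation. Plasma cell genes were lower in 11 of 13 members, with a median of -0.75 (adjusted p = 0.521 with an estimated correlation), of which Creld2 fell over all genes and 5 passed adjusted over the list alone. Alas2, Mki67, Cd3e, Spic, Col1a1 and Cdkn1a differed by 1.07, 0.01, -0.62, 0.38, 0.08 and -0.46, with limma adjusted p between 0.0976 and 0.992. Mitosis genes were lower in 34 of 46 members (median -0.11) and erythroid genes higher in 34 of 38 (median 0.66). Both lists passed camera with the preset correlation and had an adjusted p = 0.737 with an estimated correlation.

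Of 41 lists, 21 passed camera with the preset correlation, none with an estimated correlation and none by fry. The count of 218 genes was 755, 50 and 1378 without busulfan 1, 2 and 3, was 2, 2 and 7 without libraries 1, 2 and 3 of busulfan with L.J., and was 0 with the acinar score as a covariate, without the 3 libraries of high acinar score and with only the groups compared. It was 1989 with library weights, 18 without the filter and 42 for an absolute log2 difference of at least 1, and with median of ratios scaling 131 of 308 called genes were higher, against 142 of 218.

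L.J. against control asks what L.J. did without busulfan. Angptl4 rose from 3.67 ± 0.64 to 7.90 ± 0.66 FPKM (0.94, SE 0.13, limma adjusted p = 0.0453). Slc34a1 fell from 3.09 ± 1.14 to 0.36 ± 0.12 FPKM (-1.56, limma adjusted p = 0.0342) and Keg1, a gene of the kidney (gene 64697, chromosome 19, 12695790 to 12719902), from 1.52 ± 0.38 to 0.08 ± 0.08 (-1.21, adjusted p = 0.0453). These 3 were among the 4 genes called, 1 higher and 3 lower, with 1171 at an unadjusted p below the threshold. Cpt1a stood at 22.8 ± 1.26 against 15.3 ± 1.24 FPKM (0.55, limma adjusted p = 0.258), LOC105247075 at 3.38 ± 0.97 against 0.18 ± 0.16 (adjusted p = 0.0541) and Kap at 3.90 ± 0.38 against 26.9 ± 12.1 (adjusted p = 0.0714).

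Interferon-induced genes were higher with L.J. in all 47 tested members, with a median of 0.59, and 14 passed adjusted over the list alone and none over all genes. Oas1a, a sensor of double-stranded RNA, was at 12.3, 18.9 and 33.7 FPKM in the 3 L.J. libraries against 5.71 ± 1.33 in the controls (1.66, limma adjusted p = 0.548), and Usp18, a brake on interferon signalling, differed by 1.33 (adjusted p = 0.548). The list had an adjusted p = 0.69 with an estimated correlation, as did those that follow. The unfolded protein response list was higher in 27 of 29 genes (median 0.35, 8 adjusted over the list alone), that of ribosomal proteins in 63 of 77 (median 0.27, 0 adjusted over the list alone) and that of oxidative phosphorylation in 47 of 51 (median 0.30, 0 adjusted over the list alone). Heat shock genes were higher in 19 of 21 (median 0.30, 0 adjusted over the list alone), such as Hsph1, a chaperone of that family (1.04, limma adjusted p = 0.548). Acinar genes were higher in all 36 members (median 3.71), none adjusted over the list alone (adjusted p = 0.792 with an estimated correlation), and their score was highest in L.J. 3, the library with the highest interferon score of the 12 and the highest unfolded protein response score of its group. Hepatocyte genes were lower in 17 of 19 members, with a median of -1.10 and 14 adjusted over the list alone. Mki67, Alas2, Mpo, S100a8, Cd3e, Spic, Col1a1 and Cdkn1a had limma adjusted p between 0.683 and 0.987.

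Of 41 lists, 15 passed camera with the preset correlation, 12 higher and 3 lower, none with an estimated correlation and none by fry. The gene count was 8 without control 1, 0 without control 2, 1, 0 and 1 without L.J. 1, 2 and 3, 1 with quantile normalization (0 of 1 higher, against 1 of 4), 14 with library weights, 23 without the filter, 0 with a mean of at least 5 FPKM or a pseudocount of 0.1, and 1 with only the groups compared, with the acinar covariate or without the 3 libraries of high acinar score.

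Busulfan with L.J. against control shows how far mice given both stood from untreated ones. Angptl4 (1.23, SE 0.13, limma adjusted p = 0.00428) and Cpt1a (0.89, SE 0.10, limma adjusted p = 0.00649) rose, as did LOC105247075, from 0.18 ± 0.16 to 4.05 ± 0.79 FPKM (adjusted p = 0.0136). Nrgn, a calmodulin-binding protein that platelets also carry (gene 64011, chromosome 9, 37544493 to 37552745), fell from 193 ± 29.6 to 64.8 ± 9.24 FPKM (-1.55, limma adjusted p = 0.0193). Slc34a1 (-1.51), Keg1 (-1.29) and Kap, an androgen-regulated kidney protein (-3.64), fell, with limma adjusted p between 0.00421 and 0.0136. These 7 were among the 8 genes called, 3 higher and 5 lower, with 2493 at an unadjusted p below the threshold.

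Platelet genes were lower in 22 of 25 members, with a median of -0.23, of which Nrgn fell over all genes and 4 passed adjusted over the list alone (adjusted p = 0.977 with an estimated correlation). Interferon-induced genes were higher in 42 of 47, with a median of 0.41 and none adjusted over the list alone (adjusted p = 0.977 with an estimated correlation). Hepatocyte genes were lower in 17 of 19, with a median of -1.36 and 16 adjusted over the list alone (adjusted p = 0.977 with an estimated correlation). The granulocyte precursor and neutrophil lists had medians of 0.09 and 0.00, B cells -0.05, the unfolded protein response 0.15 and acinar genes 0.70, and none of these 5 lists passed camera. S100a8 stood at 187 ± 91.6 against 123 ± 45.5 FPKM (limma adjusted p = 0.805), while Mpo, Alas2, Mki67, Cd3e, Spic, Col1a1 and Cdkn1a had adjusted p between 0.25 and 0.877.

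Of 41 lists, 6 passed camera with the preset correlation, 4 higher and 2 lower, none with an estimated correlation and none by fry. The gene count was 3, 4 and 4 without libraries 1, 2 and 3 of busulfan with L.J., 20 without control 1, 3 without control 2, 1483 with library weights, 749 with only the groups compared, 30 without the filter, 4 with a mean of at least 5 FPKM and 48 without the 3 libraries of high acinar score, while the acinar covariate left it at 8.

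The interaction asks whether L.J. changed transcripts differently with and without busulfan. By limma, 0 of 13138 genes passed, with 1506 at an unadjusted p below the threshold and a smallest adjusted p of 0.0928, shared by Slpi (-4.37, SE 0.59) and Manf (-1.42, SE 0.20). Manf was lower by 1.02 on the log2 scale in busulfan-treated mice and stood at 86.1 ± 11.8 FPKM with L.J. alone against 64.7 ± 5.03 in controls. Sec11c, a subunit of the signal peptidase, differed by -1.31 (limma adjusted p = 0.0963) and Prg2 by -3.39 (adjusted p = 0.129). Gucy1a1 differed by 0.97 and Clic5, a chloride channel protein, by 1.27 (limma adjusted p = 0.129 for both). Cdkn1a, Mki67, Alas2, Mpo, S100a8, Cd3e, Spic and Col1a1 had adjusted p between 0.303 and 0.992.

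The unfolded protein response list was the 1 list with an interaction by both camera with the preset correlation and fry. In it 28 of 29 genes were negative, with a median of -0.76, and 20 passed adjusted over the list alone and none over all genes. The list passed camera with the preset correlation (adjusted p = 8.56e-19) and fry (adjusted p = 0.0493), and had an adjusted p = 0.402 with an estimated correlation. Acinar genes were negative in all 36 members (median -8.51, 31 adjusted over the list alone), neutrophil genes in 26 of 29 (median -2.99, 19 adjusted over the list alone) and plasma cell genes in 11 of 13 (median -1.34, 8 adjusted over the list alone). B cell genes were positive in 28 of 29 (median 0.70, 6 adjusted over the list alone). Each of these 4 lists had an adjusted p = 0.402 with an estimated correlation and none of them passed fry. Of 41 lists, 27 passed camera with the preset correlation, 10 positive and 17 negative, none with an estimated correlation and 1 by fry. The gene count was 511 without busulfan 3 and 220 with library weights.

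Genes that busulfan moved were set against what L.J. did in busulfan-treated mice. Across 13138 genes the differences correlated at -0.745, but the busulfan libraries enter both with opposite signs, and 1000 simulations of unchanged groups gave a mean of -0.471 with a 95% range of -0.874 to 0.219. The covariance was -0.18, against a simulated mean of -0.032 and range of -0.09 to 0.008. Over all genes 63.3% had opposite signs, where the simulation gave 66.4% (95% range 43.2 to 83.8). Genes are not independent replicates, and 3 libraries per group cannot be split into parts of 2. Part or all of the excess may therefore come from the shared libraries. The simulation drew residuals from all 12 libraries alike, while the busulfan libraries spread most. Correlations within groups were 0.915 to 0.96 for busulfan and 0.974 to 0.986 for control. The simulated ranges may thus be too narrow, and an excess over them cannot be told from chance. Slpi and Prg2 were called higher with busulfan and lower with added L.J.. Because both comparisons hold the same busulfan libraries with opposite signs, this overlap of 2 genes has no expectation from independent lists, and none was simulated.

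**Figure D3:**
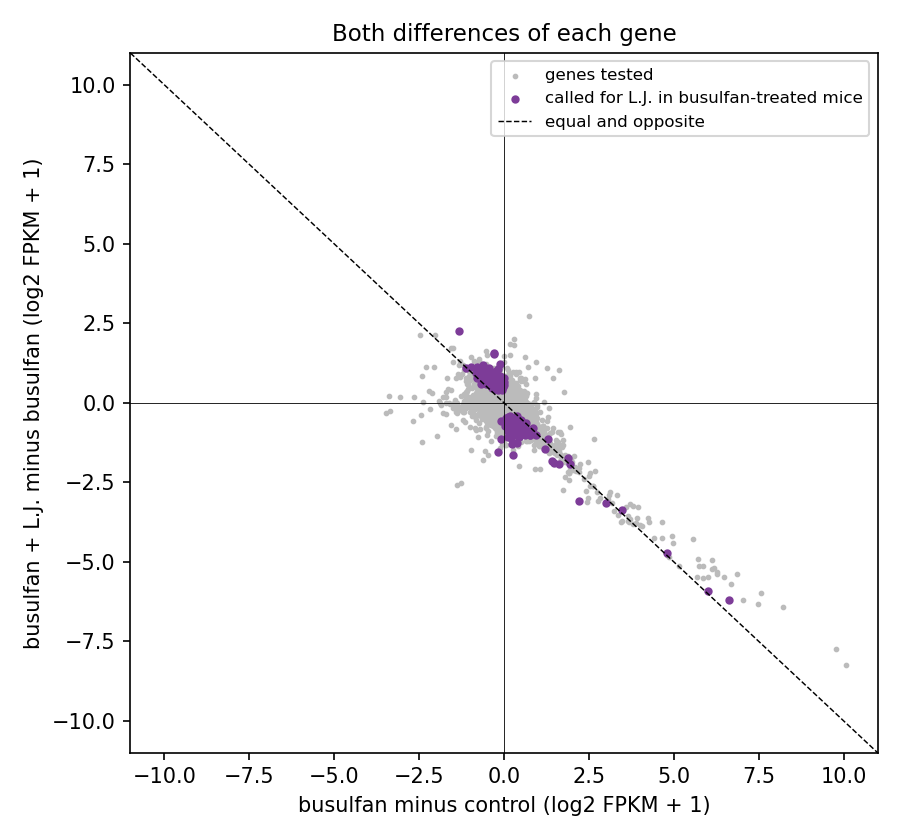
Log2 difference of busulfan with L.J. minus busulfan against that of busulfan minus control for 13138 genes, with the 218 genes called in the former marked and a dashed line where the differences are equal and opposite. Of the 142 marked genes that are higher, 140 lie below 0 on the horizontal axis, and of the 76 that are lower, 73 lie above 0.

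The 142 genes that rose with added L.J. had a median difference of 0.66 from busulfan, -0.33 between busulfan and control, and 0.34 between mice given both and control. For the 76 that fell, these medians were -0.79, 0.33 and -0.33. Among all 218, 97.7% had the opposite sign under busulfan, where the simulation gave 79.0% (95% range 34.9 to 99.1), and 2 differed from control in mice given both by the limma test, Angptl4 and Cpt1a. That count does not show a return to control. The medians against control changed sign, but they cannot decide this either. The genes were chosen by the difference between mice given both and mice given busulfan, which alone can place the controls in between. These medians were not simulated. The 8 genes called between mice given both and control also became 749 with only the groups compared and 1483 with library weights. The covariance was -0.103 without busulfan 1, -0.346 without busulfan 3, -0.316 with a pseudocount of 0.1, -0.095 with 5, -0.068 with the acinar covariate and -0.076 without the 3 libraries of high acinar score.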

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

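The tests of the acinar, granulocyte, liver and kidney patterns were chosen after the results were seen, as was the acinar score as a covariate, although the bounds for the unfolded protein response list were set before its value with that covariate was computed. The counts over other splits of the libraries were planned. Each of the 27 gene lists named here was marked because its difference with L.J. in busulfan-treated mice differed from that with L.J. alone, by camera with the preset correlation on the interaction. With an estimated correlation none of them passed (smallest adjusted p = 0.402), and with fry only the unfolded protein response did. The test for a single library far from the rest of its group was not run, since it needs at least 4 libraries, and no deposited values lay outside the comparisons.

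The negative interaction medians were -8.512 for acinar genes, -2.994 for neutrophils, -2.877 for granulocyte precursors, -1.34 for plasma cells, -0.928 for mast cells and basophils, -0.764 for the unfolded protein response and -0.672 for megakaryocytes. They were -0.573 for germinal centre B cells, -0.564 for replication-dependent histones, -0.515 for glycolysis and hypoxia, -0.395 for monocytes, -0.312 for oxidative phosphorylation and -0.245 for mitosis. Interferon response, cholesterol synthesis, ribosomal proteins and DNA replication followed at -0.236, -0.204, -0.167 and -0.164. The positive medians were 1.038 for hepatocytes, 0.701 for B cells, 0.642 for adipocytes, 0.638 for erythroid cells, 0.461 for smooth muscle, 0.43 for endothelial cells and 0.423 for natural killer cells. Antigen presentation by MHC class II, red pulp macrophages and stromal cells followed at 0.362, 0.286 and 0.267. With the acinar covariate some medians changed sign, to -0.492 for erythroid cells, -0.121 for natural killer cells and 0.458 for acinar genes. Oxidative phosphorylation and ribosomal proteins did so too, at 0.143 and 0.288.

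Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes, 1 split of 10, the real one, reached the real count with busulfan (4 genes, highest other 0), with L.J. in busulfan-treated mice (218, highest other 1), with L.J. alone (4, highest other 0) and in mice given both against control (8, highest other 1). For lists by camera with the preset correlation, 3 of 10 splits reached the real count with busulfan (25 lists, highest other 26), 4 with L.J. in busulfan-treated mice (21, highest other 25), 6 with L.J. alone (15, highest other 18) and 10 in mice given both against control (6, highest other 19). For the interaction by limma, 100 of 100 drawn splits reached the 0 genes of the real one (highest other 8, 1506 genes at an unadjusted p below 0.05 in the real one), which any split does, so this count says nothing of chance. For its lists by camera with the preset correlation, 3 of 100 gave as many (27, highest other 27). That share is under 0.05, but 2 other splits reached the real count and 0 lists passed with an estimated correlation, so chance is not taken as excluded.

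Acinar transcripts were high in busulfan libraries 1 and 2 and L.J. library 3. Busulfan as the only source is argued against, since 2 of 6 libraries without busulfan had an acinar score above the lowest busulfan library (1.89). These were L.J. 1 and L.J. 3, at 3.41 and 5.64. The controls were at 0.28 to 0.29, below all 3 busulfan libraries, so that test alone does not exclude induction by either treatment. Pancreatic tissue carried along at dissection is a candidate explanation that passed its test, as 4 of the 5 libraries with the highest acinar score were among the 5 highest for islet genes. The islet score was 0.89 in busulfan 1 and 0.24 in busulfan 2 and L.J. 3, against 0.05 to 0.08 in controls. Ins2, an insulin gene chosen after its values were seen, was at 273, 20.1 and 26.5 FPKM there, and 0 in controls. Induction of acinar genes alone predicts no islet transcripts, so these values argue against it in those 3 libraries. The islet scores of busulfan 3 and L.J. 2, 0.06 and 0.05, were like the controls. Whether the same tissue accounts for the unfolded protein response with busulfan cannot be told apart from a response of spleen cells. With the acinar score as a covariate the list median was 0.243 instead of 0.483, and the list mean 0.233 with a 95% interval of -0.071 to 0.537.

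Granulocyte transcripts were high in the same busulfan libraries 1 and 2. Cells carried over with the pancreatic tissue were tested by the slope of the neutrophil score on the acinar score among the 9 other libraries. At the upper 95% bound of that slope the acinar difference predicts a neutrophil difference of -0.017 with group means removed, and 0.717 across the libraries as they are, against 2.415 observed. These values argue against carried tissue with as few granulocytes as in those 9 libraries. Their acinar scores reached 5.64, against 8.56 in busulfan 1, and carried tissue richer in granulocytes after busulfan was not tested. More granulocytes in busulfan-treated spleens stay open as a hypothesis, since 2 of the 3 busulfan libraries exceeded all 9 others and the smallest exact p that 3 against 3 can give is 0.1. The time after treatment is not stated, so the stage of marrow loss or recovery was not tested.

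The hepatocyte score and the kidney genes Slc34a1, Keg1 and Kap had higher means in controls than in all 3 treated groups. Tissue or RNA carried into the control libraries stays open, since 72.4% of 29 kidney tubule genes had their highest mean in control (chance 25%, bounds set at 75 and 40), but the 6 that passed the filter had medians of 0.03 with busulfan and 0.008 with L.J. against control, and the kidney score of busulfan 1, 0.80, was above the 0.70 of control 2. Lower expression in the spleen cells of treated mice cannot be told apart from it, because 0 of 9 treated libraries exceeded the lowest control in the hepatocyte score, which both predict. This test replaced an earlier one on spermatid genes, a set outside the pattern, after the result of that one was seen. It had found 25 of 25 spermatid genes highest in control, 24 of them with the highest value of the 12 libraries in control 3.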

How the results depend on the processing

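The acinar score as a covariate and leaving out busulfan 1, busulfan 2 and L.J. 3 for their high acinar score were chosen after seeing the data, and the latter leaves 1 busulfan library that is assumed to vary like the other groups. The cause was not tested for any change given here. Sequencing depth is unknown, so what it limits was not examined. Scaling moved no median of all genes by over 0.1.

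Genes changed by busulfan, 4 as reported, were 107 with library weights, 24 with no filter, 2 with a mean of at least 5 FPKM, 1 with a pseudocount of 0.1, 0 with the acinar covariate, 1 without the high acinar libraries and 0 with only the groups compared, and 0 to 829 without 1 library each. Genes changed by L.J. in busulfan-treated mice, 218 as reported, were 1989 with library weights, 18 with no filter, 55 with replicate numbers as a block, 0 with the acinar covariate, 0 without the high acinar libraries, 0 with only the groups compared and 42 for a log2 change of at least 1, and 2 to 1378 without 1 library each. Genes changed by L.J. alone, 4 as reported, were 1 with quantile normalization, 14 with library weights, 23 with no filter, 0 with a mean of at least 5 FPKM, 0 with a pseudocount of 0.1, 1 with the acinar covariate, 1 without the high acinar libraries and 1 with only the groups compared, and 0 to 8 without 1 library each. Genes differing between mice given both and control, 8 as reported, were 1483 with library weights, 30 with no filter, 4 with a mean of at least 5 FPKM, 5 with the block, 48 without the high acinar libraries and 749 with only the groups compared, and 3 to 20 without 1 library each. The interaction had 220 with library weights and 0 to 511 without 1 library each.

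The replicate numbers do not pair the libraries, since 8 of 18 correlations between libraries of the same number exceeded 0.1, with a range of -0.307 to 0.325, and 5 of 12 libraries correlated best with their own number. The covariance of the reversal, -0.18 as reported, was -0.125 with no filter, -0.218 with a mean of at least 5 FPKM, -0.316 with a pseudocount of 0.1, -0.095 with 5, -0.068 with the acinar covariate and -0.076 without the high acinar libraries, and -0.346 to -0.103 without 1 library each. Lists past the threshold were 0 with an estimated correlation in all 5 comparisons, and by fry 0 in 4 and 1 in the interaction.

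Of 1827 values of list medians under alternatives, 1640 stayed, 158 were no longer past the threshold and 29 reversed. With the acinar covariate these were, for busulfan, erythroid cells 0.26, acinar -0.082, oxidative phosphorylation -0.049, ribosomal proteins -0.114 and cholesterol synthesis -0.013, for L.J. in busulfan-treated mice megakaryocytes 0.027 and acinar 0.111, for L.J. alone B cells 0.053 and acinar -0.037, and for the interaction erythroid cells -0.492, natural killer cells -0.121, acinar 0.458, oxidative phosphorylation 0.143 and ribosomal proteins 0.288. Without the high acinar libraries they were, for busulfan, mast cells -0.039, oxidative phosphorylation -0.004, ribosomal proteins -0.026 and cholesterol synthesis -0.009, for L.J. in busulfan-treated mice megakaryocytes 0.328, mast cells 0.074 and interferon -0.179, and for the interaction monocytes 0.074 and ribosomal proteins 0.123. Quantile normalization gave ribosomal proteins -0.089 for busulfan and 0.123 for the interaction, and library weights gave red pulp macrophages 0 for the interaction. Without busulfan 1, megakaryocytes were 0.056 for L.J. in busulfan-treated mice (-0.527 to 0.056 without 1 library each) and ribosomal proteins 0.007 for the interaction (-0.269 to 0.007), and without control 3 smooth muscle was 0.027 for L.J. alone (-0.259 to 0.027). For called genes that the naming rule picks, 440 of 723 values under alternatives stayed past the threshold, 283 did not and 0 reversed.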

Other observations

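The test of fatty acid genes in this part was chosen after the results were seen. A list of 28 genes of fatty acid oxidation and PPAR targets, which holds neither Angptl4 nor Cpt1a, had a median of 0.13 with L.J. in busulfan-treated mice (camera adjusted p = 0.0469 with the preset correlation, adjusted p = 0.736 with an estimated correlation), with 22 genes higher. Cd36, a fatty acid receptor (0.89), and Slc25a20, the carnitine carrier of mitochondria (0.67), rose over all genes by limma. Both were named after their values were seen. A hypothesis is that L.J. may raise this programme with or without busulfan. The list median with L.J. alone was 0.106, between the bounds of 0.05 and 0.2 set for it, and camera did not pass (adjusted p = 0.12), so the test left the hypothesis open.

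The genes Hbb-bs and Hbb-bt made up 31.6%, 0.41% and 51.1% of the FPKM of the adult beta globin genes in busulfan libraries 1 to 3, 48.8%, 0.85% and 38.8% with busulfan and L.J., 0.18%, 46.9% and 19.0% in controls, and 49.2%, 47.2% and 50.3% with L.J. Reads shared between these genes cannot be traced in FPKM values.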
